A study of Mus musculus with 12 samples.

How the data were processed

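Total RNA was sequenced from monocytes of C57Bl/6 mice, in 4 groups of 3 samples each, 12 samples in all. Ly6Chigh monocytes, also called inflammatory monocytes, and Ly6Clow monocytes, also called patrolling monocytes, came from mice given placebo or muramyl dipeptide (MDP), a fragment of bacterial peptidoglycan that is the ligand of the receptor NOD2. The titles of the MDP samples carry a time of 16 h. Those of the placebo samples read Naive and carry no time, so the titles do not show that the controls were matched in time. RNA was extracted with TRI Reagent and libraries were made by the Illumina TruSeq protocol, per the labels' protocols. The design text also names mice lacking NR4A1 or NOD2, which were not analysed here.

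The tools Trimmomatic 0.33 (a read trimmer), TopHat2 2.0.14 and Bowtie2 2.2.5 (aligners), Cufflinks 2.21 and Cuffdiff 2.21 (transcript quantification and its comparison between conditions) and the build mm10 are named by the authors, per the submitters' processing notes, with no settings. The deposited data are 2 Cuffdiff-style tables, a table for each monocyte subset, with 23996 gene rows each that were used. The tie of a table to its subset rests on the table's own name, which matches the subset words in the sample titles and source names. The deposited values of each condition are FPKM, a measure of expression scaled for transcript length and library size, with 1 value per condition and none per sample, per the file headers and the submitters' processing notes. The deposited test statistic is a score for the difference between the conditions, and the deposited p-value and q-value are the authors' own test and its adjusted form, per the file headers. No column is named for a single sample, so no SD, no leaving out of replicates, no replicate check and no depth per sample could be computed, and the depth is unknown. Whether the animals were separate for each sample is not given in the sources used here.

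The conditions inside each table are named q1 and q2. Which of them is placebo and which is MDP is not stated in the sources used here, nor whether the numbering is the same in both tables. The order was not inferred from the values or from the position of the columns. Every direction is therefore given as q2 over q1. This departs from the plan, which compared MDP with placebo. Where the plan called for placebo levels, the geometric mean of q1 and q2 was used, with each condition alone as an alternative.

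The log2 fold change was computed as log2 of the FPKM in q2 over the FPKM in q1, since the deposited column of log2 ratios holds cells that are not numbers. Genes called by the authors have a q-value under 0.05 among genes with test status OK, a rule that matched the authors' significance flag in all 23996 rows of each table. For Ly6Chigh monocytes, 11626 genes were tested, 12369 were not tested and 1 failed. For Ly6Clow monocytes, 12042 genes were tested, 11953 were not tested and 1 failed. The smallest p-value in the deposited tables is 5e-05, held by 677 genes of the Ly6Chigh table and 1440 of the Ly6Clow table. Genes at that limit share a q-value of 0.000859 in the Ly6Chigh table and 0.000418 in the Ly6Clow table.

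Gene lists and the rule for naming genes were fixed before the data were examined. The lists cover classical and patrolling monocyte genes, monocyte transcription factors, NOD2 and NF-kB feedback genes, inflammatory cytokines, regulatory and repair genes, interferon-stimulated genes, antigen presentation, cell cycle, adhesion and migration, phagocytic and pattern receptors, lipid and cholesterol handling, granule proteins, immediate early and heat shock genes and housekeeping genes, and markers of neutrophils, T cells, B cells, NK cells, dendritic cells, erythroid cells and platelets, eosinophils and basophils, and tissue macrophages. Each list was tested with a two-sided Fisher's exact test among genes called higher and among genes called lower, against tested genes with FPKM of at least 1 in either condition (10508 genes in the Ly6Chigh table, 10608 in the Ly6Clow table), with Benjamini-Hochberg adjustment over lists and directions within a subset. The median log2 fold change of each list was ranked among 10000 random lists of the same size matched on expression deciles, as a description and not as a test. Genes are not independent replicates, so these p-values describe the tables and not a population of animals. The count given as adjusted over the list alone is of measured members, higher and lower together. Each had a p under 0.05 after Benjamini-Hochberg adjustment of the authors' p-values within the list. That is a looser bar than the authors' q-value where a list holds many small p-values. List members were matched by symbol or older symbol; 5 members of these lists were not matched to a row of their own and were left out. A further 4 lists (glycolysis, cholesterol synthesis, ribosome biogenesis and oxidative phosphorylation) were chosen after seeing the data and were adjusted separately.

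Named genes were, for each subset, the 8 highest and 8 lowest log2 fold changes among called genes with FPKM of at least 1 in both conditions, leaving out rows with several symbols, predicted genes, microRNAs, small nucleolar RNAs and receptor segments. To these were added genes fixed by name whether called or not, among them Ly6c2, Ccr2, Nr4a1, Cx3cr1, Itgal, Spn, Fcgr4, Cd36, Nod2 and Ripk2, up to 4 called members of each function list with the largest change in size, the most abundant marker of each other cell type, and the 5 genes with the largest difference among those called in opposite directions.

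The planned test of the difference of the response between subsets required that a normal p computed from the deposited score lie within a factor of 2 of the deposited p-value for most genes. That held for 62.1% of genes in the Ly6Chigh table and 45.2% in the Ly6Clow table, so the difference was not tested. Overlaps of calls were set beside the number expected for independent lists and tested with Fisher's exact test across genes. The 2 tables may have been normalized separately, so no test was made across them. Levels across tables used log2 of FPKM plus a pseudocount of 1 over the 23993 rows with the same name in both, and 3 rows of each table were left out of such steps. Alternatives covered the q threshold, a fold minimum, an FPKM minimum, the set of genes over which p was adjusted, Bonferroni adjustment, the pseudocount, median centring and rows with several symbols.

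Positions are the authors' mm10 loci, written from 1. Of 22580 symbols with a single gene in GENCODE M21, 99.0% had a locus overlapping that gene. A locus can span overlapping genes. Members of close families, such as Ly6c1 and Ly6c2, Ifit3 and its copy, the Cd209 genes, the beta globins and the class II genes, can share reads, and their values are uncertain to that extent. The list tests were tested on simulated data for 10487 genes with the expression of the Ly6Chigh table. A list of 20 genes, partly genes given a simulated shift and partly random ones, reached a Fisher p of 4.59e-12. Of 200 random lists, 1% passed an unadjusted 0.05. The simulated genes varied independently and fewer of them were called than in the deposited table. The 1% therefore does not give the error rate of the list tests on the deposited values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.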

Results

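The data collected were RNA-seq profiles of 2 subsets of mouse monocytes, Ly6Chigh (inflammatory) and Ly6Clow (patrolling), from C57Bl/6 mice given placebo or muramyl dipeptide (MDP), the ligand of the intracellular receptor NOD2. The labels give 4 groups of 3 samples, and the titles of the placebo samples read Naive. The values are the authors' FPKM, 1 per condition and subset, so no replicate error can be printed beside them and the depth is unknown; the error of each difference is carried only by the authors' own q-value. The conditions of each table are named q1 and q2. Which of them is placebo and which is MDP is not stated in the sources used here, nor is it stated that the numbering is the same for both subsets, so each difference is given as higher or lower in q2 than in q1. The study's title names a conversion of Ly6Chigh into Ly6Clow monocytes after NOD2 triggering. The comparison of the 2 conditions within each subset addresses what differs between mice given MDP and mice given placebo. Matching of the controls in time is not shown by the titles. No mice lacking NOD2 were analysed here, so a difference cannot be tied to NOD2 itself.

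Subset genes set the 2 tables apart. Ly6c2, which encodes part of the Ly6C antigen that defines the subsets, was at 1312 FPKM in q1 and 1054 in q2 of the Ly6Chigh table and at 5.78 and 3.98 in the Ly6Clow table, in the authors' deposited table for each subset. Ccr2, the chemokine receptor of inflammatory monocytes, was at 581 and 278 against 80.2 and 72.6, and F13a1, coagulation factor XIII subunit A, at 456 and 255 against 6.69 and 3.36, in the authors' deposited table. In the other direction, the Fc receptor gene Fcgr4 was at 35.8 and 21.1 in the Ly6Chigh table and at 630 and 274 in the Ly6Clow table, and the scavenger receptor gene Cd36 at 5.40 and 2.98 against 190 and 195, in the authors' deposited table. Nr4a1, a nuclear receptor needed for Ly6Clow monocytes, was at 501 and 385 against 1514 and 819 in the authors' deposited table. Over 10984 genes with FPKM of at least 1 in any condition, 164 were at least 4-fold higher and 100 at least 4-fold lower in the Ly6Clow table, from the geometric mean of q1 and q2 with a pseudocount of 1. With a pseudocount of 0.1 the counts were 325 and 193, at 2-fold 580 and 477, and at 8-fold 56 and 29. These levels are set across tables that may have been normalized separately, and no test was made on them.

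**Figure D1:**
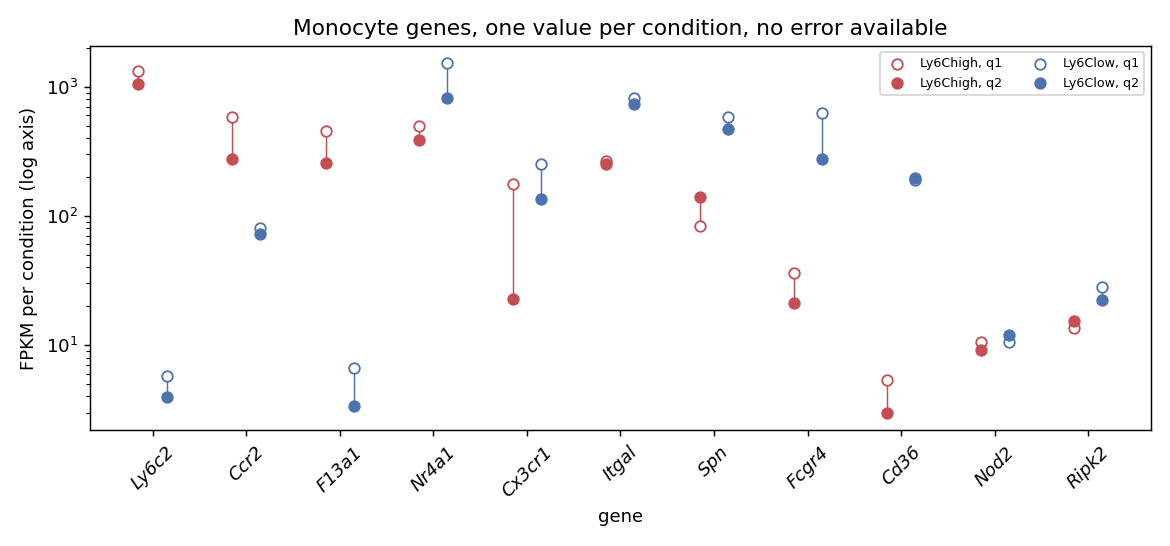
FPKM of 11 monocyte genes in conditions q1 (open) and q2 (filled) of the Ly6Chigh table (red) and the Ly6Clow table (blue), on a log axis; each point is the authors' single value for a condition, with no error bar to draw. Ly6c2 lies at 1312 and 1054 in the Ly6Chigh table and at 5.78 and 3.98 in the Ly6Clow table.

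In Ly6Chigh monocytes, interferon-stimulated and antigen presentation genes were enriched among the genes lower in q2, and cell cycle and lipid and cholesterol genes among those higher in q2. Apoe, which encodes apolipoprotein E, was 22.0-fold lower in q2, at 1013 FPKM in q1 and 46.1 in q2 (q = 0.000859 in the authors' deposited table; chromosome 7, 19696244 to 19699166, mm10, a protein-coding gene on the minus strand). Cd209a, a C-type lectin gene of dendritic cells, was 19.6-fold lower, at 62.1 and 3.17 (q = 0.000859 in the authors' deposited table; chromosome 8, 3743395 to 3748984). Fabp5, a fatty acid binding protein gene, was 15.4-fold higher, at 31.6 and 486 (q = 0.000859 in the authors' deposited table; chromosome 3, 10012585 to 10016610). In all, 1699 of 11626 tested genes were called, 822 higher and 877 lower in q2. A Bonferroni adjustment of the authors' Cuffdiff p-values left 0 calls, since the smallest deposited p-value is 5e-05, and 2945 genes had an unadjusted p under 0.05 in the authors' deposited table. At q under 0.01 the counts were 485 and 571, and with a log2 fold change of at least 1 in size they were 364 and 385.

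In Ly6Chigh monocytes, Tmem176b and Tmem176a, neighbouring membrane protein genes, were 12.9-fold and 7.96-fold lower in q2, Apoc1 11.6-fold lower and Tnfsf13b, the B cell survival factor BAFF, 9.90-fold lower in the authors' deposited table, each with q = 0.000859. The riboflavin transporter gene Slc52a3 was 14.1-fold higher, the adaptor gene Dok2 10.6-fold, Emp1 10.5-fold and the lamin A/C gene Lmna 10.2-fold higher in the authors' deposited table, each with q = 0.000859. Uck2, Dmkn and Stmn1 were 9.62-fold, 9.62-fold and 9.59-fold higher in the authors' deposited table.

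Of 22 measured interferon-stimulated genes, 20 were called lower in q2 in Ly6Chigh monocytes and 0 higher (two-sided Fisher's exact test, adjusted p = 6.92e-19). Counting both directions, 21 passed when adjusted over the list alone. Their median log2 fold change was -1.03. Ifit3 was 14.4-fold lower, Ifit2 7.92-fold and Rsad2 5.95-fold lower in the authors' deposited table, each with q = 0.000859; all 3 are induced by interferon and restrict viruses. Of 8 measured inflammatory cytokine and chemokine genes, 5 were called lower and 0 higher (exact test, adjusted p = 0.000924), 6 when adjusted over the list alone. Cxcl10, an interferon-induced chemokine, was 8.54-fold lower, Il1b 4.10-fold and Il18 2.75-fold lower in the authors' deposited table. The locus given for Cxcl10 spans 92331841 to 92414627 on chromosome 5 and can hold more than that gene. Il6 was listed at 0 in q1 and 0.394 in q2 and called higher in the authors' deposited table. Of 20 measured NOD2 and NF-kB genes, 8 were called lower and 0 higher (exact test, adjusted p = 0.00061; adjusted p = 0.0558 when calls needed q under 0.01), 8 when adjusted over the list alone. They included Nfkbiz, 2.29-fold lower, and the feedback inhibitors Nfkbia, 2.02-fold, and Tnfaip3, 1.88-fold lower, in the authors' deposited table. In both tables the locus of Nfkbia spans 55280814 to 55492647 on chromosome 12 and can hold more than that gene. Nod2 itself was at 10.5 and 9.17 FPKM (q = 0.628) and its kinase partner Ripk2 at 13.5 and 15.4 (q = 0.68) in the authors' deposited table.

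Of 17 measured antigen presentation genes, 10 were called lower in q2 and 1 higher in Ly6Chigh monocytes (exact test, adjusted p for lower = 2.46e-06), 15 in either direction when adjusted over the list alone. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 were 3.74-fold, 3.71-fold and 3.36-fold lower, and Ciita, the master regulator of class II transcription, 3.44-fold lower, in the authors' deposited table. The gene called higher was Cd80, a costimulatory ligand named after its values were seen, at 5.36 and 15.2 FPKM in the authors' deposited table. Beside this group, 3 of 5 measured dendritic cell markers were called lower and 0 higher (exact test, adjusted p = 0.0168), 4 when adjusted over the list alone. Cd209a was the most abundant of them in q1. Of 8 B cell markers 1 was called higher and 0 lower (exact test, adjusted p for higher = 0.705), 2 when adjusted over the list alone. Cd79b was at 39.5 and 26.5 FPKM (q = 0.0514 in the authors' deposited table).

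Of 19 measured cell cycle genes in Ly6Chigh monocytes, 10 were called higher in q2 and 0 lower (exact test, adjusted p = 3.58e-06), 12 when adjusted over the list alone. Top2a was at 0.308 and 2.37 FPKM and Ccnb2 at 0.78 and 4.18, low levels in the authors' deposited table, with 7.71-fold and 5.36-fold differences. In the lipid and cholesterol list 6 of 15 were higher (exact test, adjusted p = 0.0026) and 3 lower (exact test, adjusted p = 0.267), 12 when adjusted over the list alone. The median log2 fold change of that list was 0.09, at percentile 75.9 of the random lists, so the list did not move as a whole. Sqle, an enzyme of cholesterol synthesis, was 5.18-fold higher and Abca1, the cholesterol exporter, 4.76-fold lower in the authors' deposited table.

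The lists that define the subsets went both ways in Ly6Chigh monocytes. Of 20 measured patrolling genes, 5 were called higher (exact test, adjusted p = 0.0439; 0.0485 against all tested genes) and 6 lower (exact test, adjusted p = 0.0151), 13 when adjusted over the list alone. The integrin gene Itgax was 3.18-fold higher and Spn, which encodes CD43, 1.69-fold higher, while the fractalkine receptor gene Cx3cr1 was 7.76-fold lower, Pparg 3.95-fold lower, Fcgr4 1.70-fold and Cd36 1.81-fold lower in the authors' deposited table. Of 16 classical monocyte genes, 4 were lower and 1 higher (exact test, adjusted p for lower = 0.0947), 10 when adjusted over the list alone. Ccr2 was 2.09-fold lower and Vcan, a matrix proteoglycan gene, 3.76-fold higher in the authors' deposited table. Ly6c2 (q = 0.345), Itgal (q = 0.886) and Nr4a1 (q = 0.244) did not pass the threshold in the authors' deposited table. Of 17 measured transcription factors, 3 were lower and 1 higher (exact test, adjusted p for lower = 0.333), 6 when adjusted over the list alone. Cebpb was 2.47-fold higher and Cebpa 1.95-fold lower in the authors' deposited table.

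Of 18 phagocytic and pattern receptor genes in Ly6Chigh monocytes, 8 were lower and 1 higher in q2 (exact test, adjusted p for lower = 0.000367), 11 when adjusted over the list alone. The phagocytic receptor gene Axl was 6.81-fold lower and Mertk 3.40-fold higher in the authors' deposited table. Of 11 regulatory and repair genes 4 were lower and 1 higher (exact test, adjusted p for lower = 0.029), 6 when adjusted over the list alone. The median log2 fold change of that list was -0.08, at percentile 29.7 of the random lists, so the list did not move as a whole. Adhesion and migration genes were 4 lower and 2 higher of 18 (exact test, adjusted p for lower = 0.132), 7 when adjusted over the list alone, and granule protein genes 1 lower and 1 higher of 8 (exact test, adjusted p for higher = 0.705), 4 when adjusted over the list alone. Among immediate early and heat shock genes, which respond to handling, 6 of 11 were lower and 2 higher (exact test, adjusted p for lower = 0.00061), 10 when adjusted over the list alone. Fos was 3.61-fold and Egr1 2.99-fold lower in the authors' deposited table. Of 10 housekeeping genes 3 were higher and 0 lower (exact test, adjusted p = 0.0947; 0.0275 when calls needed q under 0.01), 4 when adjusted over the list alone. Gapdh was 2.41-fold higher in the authors' deposited table. Among markers of other cells, neutrophil markers were 3 higher and 1 lower of 5 (exact test, adjusted p for higher = 0.0151), 4 when adjusted over the list alone. S100a8 was 6.71-fold higher and Csf3r, a receptor gene chosen after its values were seen, 2.17-fold lower in the authors' deposited table. Tissue macrophage markers were 3 higher and 1 lower of 5 (exact test, adjusted p for higher = 0.0151), 5 when adjusted over the list alone. Emr1, a macrophage surface receptor gene, was 2.10-fold lower in the authors' deposited table. The 3 markers called higher were the complement genes C1qa, C1qb and C1qc, named after their values were seen. NK cell markers were 1 lower of 2 (exact test, adjusted p = 0.333), 1 when adjusted over the list alone. Erythroid and platelet markers were 2 lower of 7 (exact test, adjusted p = 0.257), 2 when adjusted over the list alone. The most abundant of them, the beta globin gene Hbb-bt, was at 210 and 234 FPKM (q = 0.703) in the authors' deposited table. Of 5 T cell markers 0 were called, 0 when adjusted over the list alone, and 0 eosinophil and basophil markers reached the FPKM minimum.

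**Figure D2:**
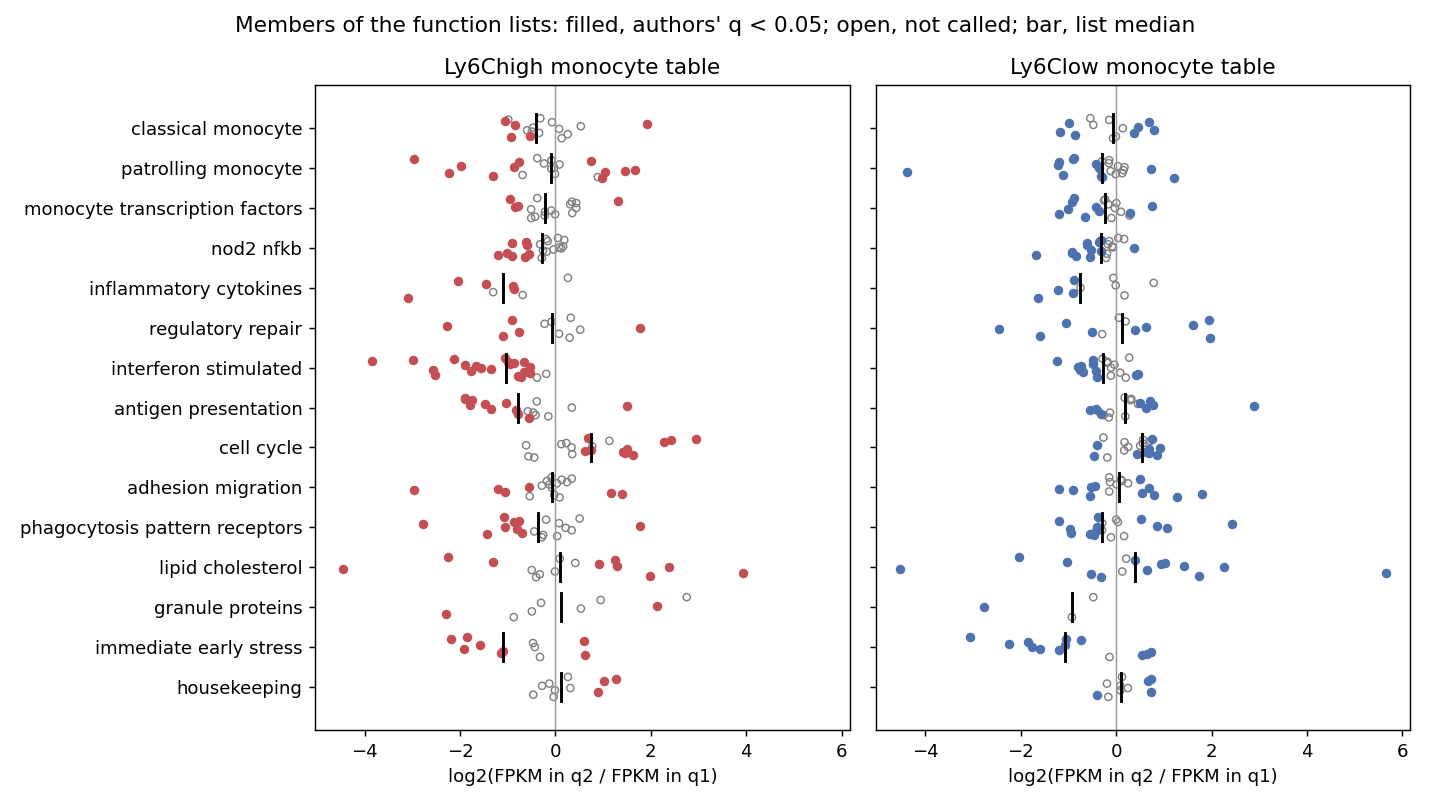
Log2 of FPKM in q2 over FPKM in q1 (x axis) for the measured members of the 15 function lists (y axis) in the Ly6Chigh table (left) and the Ly6Clow table (right); filled points passed the authors' q-value threshold of 0.05, open points did not, and the black bar is the list median. The interferon-stimulated genes have a median of -1.03 on the left and -0.28 on the right.

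In Ly6Clow monocytes, immediate early, NOD2 and NF-kB, patrolling and interferon-stimulated genes were enriched among the genes lower in q2, and lipid and cholesterol genes among those higher. Ccl17, a chemokine that attracts T cells, was 216-fold higher, at 1.61 FPKM in q1 and 347 in q2 (q = 0.000418 in the authors' deposited table; chromosome 8, 94810453 to 94812036). Fabp5 was 50.6-fold higher, at 14.7 and 742, and Apoe 23.1-fold lower, at 2767 and 120, in the authors' deposited table, each with q = 0.000418. Of 12042 tested genes, 3172 were called, 1706 higher and 1466 lower in q2. Bonferroni adjustment of the Cuffdiff p-values left 0 calls, with 4335 genes at an unadjusted p under 0.05 in the authors' deposited table. With a log2 fold change of at least 1 in size, 394 and 271 genes passed both criteria.

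Among the other genes of the naming rule in Ly6Clow monocytes, the acute phase gene Saa3 was 13.7-fold higher, the protease inhibitor gene Spint1 13.5-fold, Slc52a3 11.1-fold, the transcription factor gene Gfi1b 10.6-fold and the actin capping gene Capg 9.30-fold higher in the authors' deposited table. The lectin receptor gene Clec4n was at 64.9 FPKM in q2 and called higher in the authors' deposited table. Apoc2 was 20.7-fold lower, Fos 8.37-fold, the lipid-sensing receptor gene Trem2 7.10-fold, Dmpk 6.87-fold, Cd163 5.51-fold, Egr1 4.77-fold and Cd83 4.71-fold lower in the authors' deposited table. Each of these has q = 0.000418 in the authors' deposited table.

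Of 21 measured patrolling genes in Ly6Clow monocytes, 10 were called lower in q2 and 2 higher (exact test, adjusted p for lower = 0.0012), 12 when adjusted over the list alone. Fcgr4 was 2.30-fold lower, Pparg 2.34-fold, Nr4a1 1.85-fold and Cx3cr1 1.87-fold lower, and the tetraspanin gene Cd9 2.30-fold higher in the authors' deposited table. Cd36 (q = 0.861), Itgal (q = 0.646) and Spn (q = 0.117) did not pass in the authors' deposited table. Transcription factor genes were 7 lower and 2 higher of 17 (exact test, adjusted p for lower = 0.0191; 0.0502 when calls needed q under 0.01), 11 when adjusted over the list alone. The Notch target Hes1 was 2.28-fold lower and Bcl6 was called lower at 145 and 72.3 FPKM in the authors' deposited table. Classical genes were 4 higher and 3 lower of 13 (exact test, adjusted p for higher = 0.247), 9 when adjusted over the list alone. Plac8 was 1.74-fold higher in the authors' deposited table, while Ccr2 (q = 0.37) and Ly6c2 (q = 0.0815) did not pass.

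NOD2 and NF-kB genes in Ly6Clow monocytes were 11 lower and 1 higher of 20 (exact test, adjusted p for lower = 0.000183), 12 when adjusted over the list alone. Nfkbiz was 3.18-fold lower, Nfkbia 1.90-fold and Relb 1.89-fold lower, Ripk2 was 1.25-fold lower (q = 0.0244), and Nod2 was at 10.6 and 11.9 FPKM (q = 0.292) in the authors' deposited table. Interferon-stimulated genes were 10 lower and 2 higher of 21 (exact test, adjusted p for lower = 0.0012), 12 when adjusted over the list alone, with a median log2 fold change of -0.28. Ifit3 was 2.35-fold lower in the authors' deposited table. Inflammatory cytokine genes were 4 lower and 0 higher of 9 (exact test, adjusted p = 0.0664), 4 when adjusted over the list alone. Cxcl2 was 3.09-fold and Ccl3 2.33-fold lower in the authors' deposited table.

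Antigen presentation genes in Ly6Clow monocytes were 5 higher and 3 lower of 17 (exact test, adjusted p for higher = 0.215), 12 when adjusted over the list alone. Cd80 was 7.47-fold higher, Ciita 1.71-fold and H2-DMa 1.64-fold higher in the authors' deposited table. Markers of B cells, which carry class II, were 6 higher and 0 lower of 9 (exact test, adjusted p = 0.00443), 8 when adjusted over the list alone. Cd79b was at 64.9 and 92.4 FPKM in the authors' deposited table. Dendritic cell markers were 4 higher and 2 lower of 6 (exact test, adjusted p for higher = 0.0283), 6 when adjusted over the list alone. Cd209a was at 129 and 194 FPKM in the authors' deposited table.

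Lipid and cholesterol genes in Ly6Clow monocytes were 8 higher and 5 lower of 15 (exact test, adjusted p for higher = 0.00443), 13 when adjusted over the list alone. Sqle was 4.82-fold higher and Abca1 4.12-fold lower in the authors' deposited table. Cell cycle genes were 7 higher and 2 lower of 18 (exact test, adjusted p for higher = 0.0439), 12 when adjusted over the list alone. Mcm2, a replication licensing factor, was 1.90-fold higher in the authors' deposited table. Phagocytic and pattern receptors were 8 lower and 4 higher of 18 (exact test, adjusted p for lower = 0.00612), 13 when adjusted over the list alone. Tlr2 was 1.94-fold lower and the scavenger receptor gene Marco 5.38-fold higher in the authors' deposited table. Regulatory and repair genes were 5 higher and 4 lower of 12 (exact test, adjusted p for higher = 0.0687; 0.0248 when calls needed q under 0.01), 9 when adjusted over the list alone. Il1rn, an antagonist of interleukin 1, was 3.06-fold higher in the authors' deposited table. Adhesion and migration genes were 6 higher and 5 lower of 18 (exact test, adjusted p for higher = 0.106), 12 when adjusted over the list alone. Pecam1 was 2.41-fold higher and Cxcr4 2.28-fold lower in the authors' deposited table. Granule protein genes were 1 lower of 3 (exact test, adjusted p = 0.547), 3 when adjusted over the list alone, and housekeeping genes 3 higher and 1 lower of 10 (exact test, adjusted p for higher = 0.333), 4 when adjusted over the list alone.

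Immediate early and heat shock genes in Ly6Clow monocytes were 9 lower and 3 higher of 13 (exact test, adjusted p for lower = 0.00018), 12 when adjusted over the list alone. Neutrophil markers were 3 higher and 1 lower of 4 (exact test, adjusted p for higher = 0.0439; 0.11 against all tested genes and 0.131 when calls needed q under 0.01), 4 when adjusted over the list alone. NK cell markers were 4 higher of 8 (exact test, adjusted p = 0.0664), 4 when adjusted over the list alone, and tissue macrophage markers 4 lower and 1 higher of 7 (exact test, adjusted p for lower = 0.0311), 7 when adjusted over the list alone. The 4 macrophage markers called lower were Emr1, C1qa, C1qb and C1qc, the last 3 named after their values were seen. Erythroid and platelet markers were 2 higher and 1 lower of 7 (exact test, adjusted p for higher = 0.49), 3 when adjusted over the list alone. The most abundant of them, Hbb-bt, was at 387 and 529 FPKM and called higher (q = 0.000788) in the authors' deposited table. T cell markers were 1 higher of 4 (exact test, adjusted p = 0.639), 1 when adjusted over the list alone. The only measured eosinophil and basophil marker, Ccr3, was 3.51-fold higher in the authors' deposited table (exact test, adjusted p = 0.309), 1 when adjusted over the list alone.

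If q1 and q2 have the same meaning in both tables, the calls of the subsets overlapped more than independent lists would; if the numbering were crossed, same and opposite directions would change places. Among 10179 genes tested in both with FPKM of at least 1, 508 were called higher in both and 481 lower in both. Independent lists of those sizes would share 106 and 99.4 (two-sided Fisher's exact test across genes, p = 2.68e-279 and 1.45e-257). Apoe, Fabp5, Slc52a3, Uck2, Sqle, Abca1 and Nfkbiz were among the genes called in the same direction. A further 58 genes were called in opposite directions, against 207 for independent lists; 20 were higher in Ly6Chigh and lower in Ly6Clow monocytes and 38 the reverse. At q under 0.01, 624 genes were called in the same direction and 23 in opposite directions. Across 10163 genes the log2 fold changes had a Pearson correlation of 0.63 and a Spearman correlation of 0.61; these are across genes, which are not independent replicates. The 2 comparisons share no libraries by the labels. The sample titles number the samples of both subsets alike. Whether both subsets came from the same mice is not given in the sources used here. If they did, a difference between mice could enter both comparisons and add to the overlap and the correlation.

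**Figure D3:**
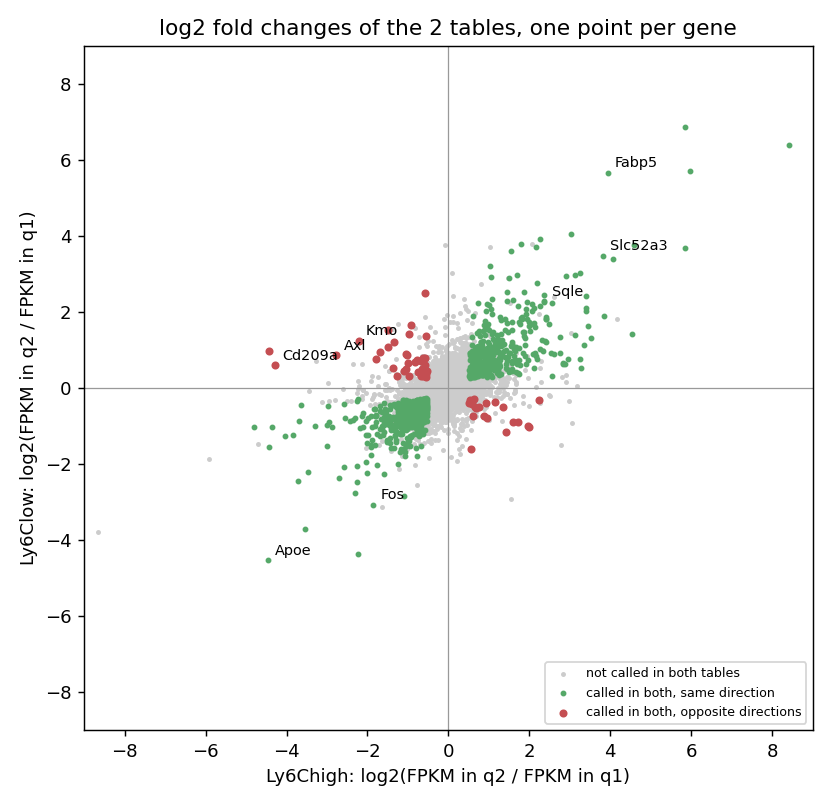
Log2 of FPKM in q2 over FPKM in q1 in the Ly6Chigh table (x axis) against the Ly6Clow table (y axis), with a point for each gene with FPKM of at least 1 in both; green points were called in the same direction in both tables, red points in opposite directions, grey points were not called in both, and 2 genes lie beyond the axes. Most genes called in both tables, 94.5%, were called in the same direction.

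Genes called in opposite directions included Cd209a, Cd209d, Axl, Kmo and Ifi205. Cd209d was 21.5-fold lower in q2 in Ly6Chigh monocytes (q = 0.0334) and 1.96-fold higher in Ly6Clow monocytes (q = 0.000418) in the authors' deposited table. In Ly6Chigh monocytes Cd209d was at 5.56 and 0.259 FPKM, so the size of that fold rests on a low value in q2. Axl was 6.81-fold lower and 1.82-fold higher, and Kmo, an enzyme of tryptophan breakdown, 4.66-fold lower and 2.38-fold higher in the authors' deposited table. The interferon-inducible gene Ifi205 was at 26.6 and 17.7 FPKM, called lower, in Ly6Chigh monocytes and 5.70-fold higher in Ly6Clow monocytes in the authors' deposited table. The Ly6Chigh calls of Cd209d and Ifi205 (q = 0.0334 and 0.0445 in the authors' deposited table) were lost at q under 0.01. The planned test of a difference between the responses of the subsets was not made, because the deposited score and p-value did not meet the condition set for it.

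Genes that set the subsets apart address whether the Ly6Chigh profile differs between the conditions in the direction of Ly6Clow monocytes. Each set below is the part of the 164 or 100 genes above that was tested in the table named, with FPKM above 0 in both its conditions, so the counts differ between the tables. The 133 such genes at least 4-fold higher in the Ly6Clow table had a median log2 fold change of -0.13 in the Ly6Chigh table, with 30 called higher and 39 lower in q2. The 96 such genes at least 4-fold lower in the Ly6Clow table had a median of -0.11, with 18 called higher and 25 lower. In all, 46.6% of the first set and 42.7% of the second were higher in q2. These medians lay at percentiles 0.295 and 0.29 of 10000 random lists matched on expression. The sign of each median depended on the condition used to define the genes. With q1 of the Ly6Chigh table as the reference the medians were 0.53 and -0.59, and with q2 they were -0.71 and 0.53, where that condition enters both the definition and the fold change. With q1 of the Ly6Clow table, which does not enter the fold change, the medians were -0.28 and 0.060, and with its q2 they were 0.031 and -0.44. In the Ly6Clow table, the 82 such genes at least 4-fold higher in Ly6Chigh had a median of 0.24, with 32 called higher and 17 lower, and the 158 such genes at least 4-fold lower had a median of -0.23, with 31 called higher and 66 lower. These medians lay at percentiles 100 and 0 of the random lists. No single-condition reference was run for these.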

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

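The tests of causes in this part were chosen after the result was seen. Directions rest on the condition that q1 and q2 have the same meaning in both tables, which is not stated in the sources used here; if the numbering were crossed, the genes listed as opposite would be shared and the shared genes opposite.

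Genes called by the authors in opposite directions in the 2 subsets numbered 58, and 23 at q under 0.01. Each passed the authors' test in its own table with a different sign, and the size of the difference itself was not tested. Among the genes of the naming rule, the difference of log2 fold change, Ly6Chigh minus Ly6Clow, was -5.39 for Cd209d, -4.88 for Cd209a, -3.63 for Axl, -3.47 for Kmo, -3.10 for Ifi205, -2.65 for Gzma, -2.56 for Ciita and -1.53 for Irf4. The Ly6Chigh calls of Cd209d, Ifi205 and Gzma were lost at q under 0.01. Among genes outside that rule, chosen after their values were seen, it was 3.01 for C1qc, 2.96 for C1qa, 2.61 for C1qb, 1.34 for Jun, 1.21 for Jund and -1.54 for H2-DMb1. The NK cell gene Gzma was at 4.11 and 1.27 FPKM in Ly6Chigh monocytes and 10.4 and 20.1 in Ly6Clow monocytes, and Irf4, a transcription factor of dendritic cells, at 21.9 and 12.7 against 12.2 and 20.5, in the authors' deposited table.

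The pattern weighed first is the lower class II expression in q2 of the Ly6Chigh table. The 6 class II genes H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1 and Cd74 had a median log2 fold change of -1.61 there and 0.39 in the Ly6Clow table. Fewer B cells among the cells sampled would lower the B cell markers to a like extent, but the 8 measured markers had a median of -0.28 and a lowest value of -0.58, which argues against B cells as the whole cause; Cd79b, the most abundant, was at 39.5 and 26.5 FPKM in the authors' deposited table. Fewer dendritic cells, or fewer monocytes that carry their genes, may account for part of it: the 5 measured dendritic cell markers had a median of -4.29, but they ranged from -4.80 to -0.51, with Cd209a at 62.1 and 3.17 FPKM in the authors' deposited table, so loss of such cells and lower expression within the monocytes cannot be told apart. An effect of the treatment stays open as well, and its direction is not known here. In the Ly6Clow table the B cell markers had a median of 0.50, with 6 called higher and 0 lower. The dendritic cell markers had a median of 0.60 there, with 4 called higher and 2 lower. Both medians lay above the class II median of 0.39. More of such cells may therefore account for the class II difference in that table, which was not tested.

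The pattern weighed next is the lower median of the list of immediate early and heat shock genes in q2, at -1.10 in the Ly6Chigh table and -1.08 in the Ly6Clow table. Members that went the other way, chosen after their values were seen, were Jun and Hsp90aa1, called higher in the Ly6Chigh table at 0.60 and 0.62, and Hspa1a, Hspa1b and Hsp90aa1, called higher in the Ly6Clow table at 0.73, 0.65 and 0.54. Jun was called lower in the Ly6Clow table at -0.74. Outside the list, Jund was called higher in the Ly6Chigh table at 0.68 and lower in the Ly6Clow table at -0.53. A scaling difference that is a single factor for all genes would move the list and the other genes alike and leave the distance between them as it was. The medians of all genes with FPKM of at least 1 were 0.0089 and -0.0031, and the list medians minus these were -1.11 and -1.07. The list medians lay at percentile 0 of the random lists matched on expression in both tables. By its definition such a factor could not make this distance or alter this rank, whatever the values, so the comparison is not a test of it. Less stress during handling may lower such genes, and if it lowered heat shock genes as well they would be under 0. Their medians over 4 genes were 0.24 in the Ly6Chigh table and 0.59 in the Ly6Clow table. Only 11 of the 13 list members had FPKM of at least 1 in the Ly6Chigh table. The heat shock median there may include genes below that level. Dnajb1 was at -0.32 and -0.14, so this form of handling stress is not decided. A handling difference that acts on the immediate early genes alone and an effect of the treatment cannot be told apart, since the conditions are the only grouping in the tables.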

How the results depend on the processing

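Alternatives fixed before the data were examined were run wherever the deposited values allowed; the single-condition levels, the single conditions of the Ly6Clow table in the signature and the correlation without 2 extreme genes were added after seeing the data. No paired analysis was possible because the tables hold 1 value per condition and no column for a sample. For the same reason a pseudocount of 0.1 or no filter on sample values, a replicate block, leaving out each replicate and other splits of the samples were not run, and since the depth is unknown, what it limits cannot be given. The test of the difference between responses and its alternatives, under 0.01 and with an FPKM minimum, were not run because its condition was not met.

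Calls higher and lower in q2 kept within 1.5 times of their counts with an FPKM minimum of 1, with q recomputed over those genes and with 1 symbol per row, in both tables. At q under 0.01 the Ly6Chigh counts were 485 and 571, and the Ly6Clow counts stayed within 1.5 times. With a log2 fold change of at least 1 in size they were 364 and 385 (Ly6Chigh) and 394 and 271 (Ly6Clow), with a pseudocount of 1 on that scale 227 and 229, and 185 and 117, and after median centring 361 and 393, and 398 and 269, fewer because a second criterion was added. Bonferroni adjustment gave 0 in each case, since 5e-05 is the smallest deposited p-value. The median of all genes was within 0.01 of 0 in both tables. At q under 0.01, genes called in the same direction numbered 624 and in opposite directions 23. With no FPKM minimum the Pearson correlation was 0.45; it was 0.62 without 2 extreme genes, 0.68 at FPKM of at least 5 and 0.58 with a pseudocount of 1.

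Levels between the tables gave 580 higher and 477 lower genes at 2-fold, 56 and 29 at 8-fold, and 325 and 193 with a pseudocount of 0.1. For the signature in Ly6Chigh monocytes, the medians of the genes higher and lower in Ly6Clow were 0.53 and -0.59 with q1 of the Ly6Chigh table as the reference and -0.71 and 0.53 with q2, where the reference enters the fold change as well. With q1 of the Ly6Clow table they were -0.28 and 0.060, and with q2 0.031 and -0.44; the cause was not tested. Enriched lists and directions numbered 26, 25 against all tested genes and 25 at q under 0.01. Of the single genes named, 9 lost their call at q under 0.01 (Birc5, Cd209d, Gzma and Ifi205 in the Ly6Chigh table and Ccl4, Ccnb1, Cdk1, Cebpd and Ripk2 in the Ly6Clow table), and with q recomputed 4 lost it and 1, Cd79b in the Ly6Chigh table, gained it. Of these named genes none changed sign with a pseudocount of 1 or median centring.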

Other observations

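The 4 lists in this part and their tests were chosen after other genes of the data had been seen, and the examples after their own values had been seen. Cholesterol synthesis genes beyond the fixed lists were higher in q2 in both subsets. Of 19 measured enzymes and regulators of the pathway, 16 were called higher and 0 lower in Ly6Chigh monocytes (two-sided Fisher's exact test, adjusted p = 4.43e-15) and 17 higher and 0 lower in Ly6Clow monocytes (exact test, adjusted p = 7.16e-12), with median log2 fold changes of 1.24 and 1.40. Fdps, farnesyl diphosphate synthase, was at 39.5 and 189 FPKM in Ly6Chigh monocytes and at 33.7 and 152 in Ly6Clow monocytes, and Idi1 at 8.74 and 36.8 against 9.94 and 40.3, in the authors' deposited table. The list was chosen after genes of the fixed lipid and cholesterol list had been seen, and the values of its own members had not been seen.

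The complement genes C1qa, C1qb and C1qc are members of the fixed list of tissue macrophage markers and make up 3 of the 3 markers of that list called higher in Ly6Chigh monocytes and 3 of the 4 called lower in Ly6Clow monocytes. Chosen after their values were seen, they were called higher in q2 in Ly6Chigh monocytes and lower in Ly6Clow monocytes. C1qb was at 10.8 and 35.9 FPKM in Ly6Chigh monocytes and at 45.6 and 24.7 in Ly6Clow monocytes in the authors' deposited table. No explanation was tested.

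The hypothesis that 4 metabolic processes are together higher in q2 in both subsets was examined with lists whose members had not been seen; the adjusted p-values are over these 4 lists alone. The lower of the 2 percentiles of the list median among random lists was 100 for cholesterol synthesis, 99.94 for glycolysis, 99.81 for oxidative phosphorylation and 99.5 for ribosome biogenesis. Each lay above the bound written beforehand, but such a rank describes the median of a list and is not a test of its genes. Glycolysis genes were 7 higher and 2 lower of 13 in Ly6Chigh monocytes (exact test, adjusted p for higher = 5.49e-05) and 8 higher and 1 lower of 13 in Ly6Clow monocytes (exact test, adjusted p for higher = 0.000381). Oxidative phosphorylation genes were 8 higher of 20 (exact test, adjusted p = 0.000131) and 11 higher of 20 (exact test, adjusted p = 0.00013), with 0 lower. Ribosome biogenesis genes were 0 of 20 in Ly6Chigh monocytes (exact test, adjusted p = 0.399) and 8 higher of 20 in Ly6Clow monocytes (exact test, adjusted p = 0.0107; 0.113 when calls needed q under 0.01). The exact tests passed 0.05 for genes higher in both subsets for 3 of the 4 lists; for ribosome biogenesis in Ly6Chigh monocytes the rank alone was high and no gene was called. Whether the differences of those 3 lists follow MDP or its absence is not known here, since the order of the conditions is not stated in the sources used. If the numbering were crossed between the tables, each of these lists would go in opposite directions in the 2 subsets.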
